A study of Mus musculus with 160 samples.

How the data were processed

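Gene expression was measured in mouse tumors by 3′ tag sequencing of mRNA. Per the labels' protocols, total RNA came from fresh frozen or from formalin-fixed, paraffin-embedded (FFPE) tissue, libraries were made with the Lexogen QuantSeq kit, and pools were sequenced on an Illumina HiSeq4000 or NovaSeq6000. The labels state that frozen and fixed samples were only compared among their own kind, but not which sample is which, nor which instrument read it. The labels list 160 samples in 25 groups. Titles carry a number per sample, and nothing in the labels says that the samples of a group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

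The deposited values are scores. In each row the authors' tables give the distance of a library from the row's mean in units of the row's SD, as read from the values, and the authors' normalization and standardisation are not given in the sources used here. Per the submitters' processing notes, FastQC 0.11.4, STAR 2.7.0 and RSEM 1.3.1 and the builds GRCm38 and mm10 were used, with no order or role stated. There were 3 tables. The arms table holds B16F10 and KP tumors after each treatment arm (118 columns used, 43783 rows), the transfer table B16F10 tumors after transfer of different cells (21 columns, 37017 rows), and the lung table autochthonous lung tumors (20 columns, 23236 rows). Rows of the arms table carry no gene name or identifier, so results from it are counts of rows. The largest scores show that the arms table was standardised over 188 libraries and the transfer table over 28, so 70 and 7 further libraries entered the standardisation and are not analysed here. Of the per-sample columns, 1 (KP lymphodepletion 93) holds 38669 cells of spreadsheet errors and was not used.

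Normalized read counts were recovered from the scores before testing. Within a row, distances between libraries are whole multiples of a single step per library on a linear scale, so rows with few reads gave each library's size factor, and a lattice reduction then gave the reads of each row. A value was taken as recovered within 0.02 steps of a whole number, a tolerance that grew with the count to at most 0.05. A row was kept only where every library met it, so 100% of the values of recovered rows do so by that rule. Recovered were 41957 rows of the arms table, 35741 of the transfer table and 22944 of the lung table; 1600 arms rows had the same value in all libraries. Among rows above their lowest value in more than 3 libraries, 99.9655% of arms rows, 99.9964% of transfer rows and 99.9886% of lung rows were recovered. Steps were taken as hundredths of a read in 16232 arms rows, 9574 transfer rows and 5722 lung rows, as an estimate that splits reads between locations gives; for 264, 1397 and 722 of these the choice rests on their level alone. Values of such genes are uncertain, because near-identical or overlapping genes may share their reads or the step may be wrong, and the text says so as "split reads". For some genes the step could be a read or a fraction of it, and these are given as fold changes without a level. On simulated scores with known reads, the recovery returned 99.9023% of 41952 arms rows, 99.6511% of 34109 transfer rows and 99.677% of 21675 lung rows, and of those 99.9523%, 99.747% and 99.7315% exactly up to the unit. The right unit was given to 97.5448%, 98.4848% and 98.3106% of the recovered rows, with 95.8951% to 99.3083% of rows in hundredths and 96.4347% to 99.1415% of rows in whole reads.

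In the lung table the first 9989 rows hold 10 columns in another order within their groups than the remaining 13247 rows, as the recovered size factors show; the columns were put into 1 order, with no column moved to another group. Rows without a symbol (32 transfer, 31 lung) and 27 transfer symbols that a spreadsheet had turned into dates are never named. Recovered totals were 0.108 to 14.7 M reads per library in the arms table (median 5.48), 3.50 to 9.005 in the transfer table (median 6.49) and 1.98 to 6.17 in the lung table (median 3.79). Libraries of 1 group never matched within sampling noise. Over 149 pairs of B16, 308 of KP, 44 of transfer and 63 of lung libraries, the lowest ratio of the squared difference to sampling noise was 11.7, 10.3, 11.6 and 15.3.

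The design written before the data were examined foresaw counts or normalized values. Since the deposited unit is a score, the test it named for normalized values was used on the recovered values. Tests were made with limma 3.58.1 (lmFit, then eBayes with trend and robust) on log2(normalized count + 1) in R 4.3.3. Rows entered where at least as many libraries as in the smallest group reached 1. All groups of a model or table shared 1 fit with a mean per group. P-values were adjusted by the Benjamini-Hochberg method, and a row was called at an adjusted p of 0.05. Fold changes are on the log2(count + 1) scale, which understates those of low genes. In all, 28 comparisons of groups and the difference of the TRI-IT response between models were tested. Correlations of fold changes between models were taken across rows, with 100 bootstraps of libraries.

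Named genes follow a rule fixed in that first design. It takes, among called genes at or above the median expression, the 8 with the largest rise and the 8 with the largest fall in main comparisons (3 and 3 in the others), without predicted genes, then members of fixed lists with the smallest adjusted p or the highest expression, and a set of fixed genes. Where a comparison had 5 or fewer calls, all are named, chosen after their values were seen. Of the genes that the rule names, 1 is not reported here. The 30 gene lists (397 genes) were also fixed there. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. Fry asks whether a list's genes move one way, without reference to other genes. Coordinates are GRCm38 positions of the same symbols in GENCODE release M21.

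The fit was tested on simulated counts with 200 changed genes per comparison. At 2-fold, 4-fold and 8-fold changes it recovered 11.9%, 37.3% and 72.7% for B16 TRI-IT against control (28176 rows in the step) and 56.7%, 86.6% and 89.4% for KP TRI-IT against control (29394 rows). For the transfer table (28871 genes) the shares were 65.7%, 85.1% and 93.9% against gamma-delta T cells, 58.2%, 71.6% and 92.4% against LAK cells, 52.2%, 77.6% and 86.4% against CTLs, and 35.8%, 77.6% and 89.4% against CIK cells. For the lung table (16117 genes) they were 34.3%, 83.6% and 90.9% for inhaled TRI-IT against anti-PD1, 32.8%, 80.6% and 87.9% for subcutaneous TRI-IT against anti-PD1, and 46.3%, 86.6% and 93.9% for inhaled against subcutaneous TRI-IT. False calls made up 4.71%, 6.06%, 4.68%, 6.33%, 8.86%, 11.8%, 4.14%, 9.46% and 3.21% of the calls in these comparisons, in the order given. The simulation drew each gene on its own, without any structure shared between libraries. These shares therefore do not cover false calls that such a structure would cause. Only genes at or above the median level were changed, so the recovered shares do not hold for lower genes.

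Alternatives planned in that first design were quantile normalization, no filter on low values, a pseudocount of 0.1, a fit on the compared groups alone, leaving out libraries under 0.25 of the median total, the replicate number as a block in the transfer table, and leaving out each replicate of groups of up to 5. Added after seeing the data were limma on the scores as deposited, limma-voom on the recovered reads, fits without libraries that stand apart, fits within a series of title numbers or with the series as a term, fits without single lymphodepletion libraries, and lung columns in their named order. Sample relations used permutation tests with 100000 resamples, and regroupings of the samples were limited to 100. Other tools were statmod 1.5.0 and data.table (1.17.8) in R, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.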

Results

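Tumor mRNA was profiled in mice given a combination immunotherapy called TRI-IT, its parts, or other cell transfers. TRI-IT joins adoptive cell transfer (ACT), an antibody against the checkpoint receptor PD1 and a mix of Toll-like receptor (TLR) agonists, given after lymphodepletion; the triple arm is the same treatment without lymphodepletion. The transfer table held 21 libraries of subcutaneous B16F10 melanoma after combined ACT (4) or after gamma-delta T cells (8), lymphokine activated killer (LAK) cells (4), cytotoxic T lymphocytes (CTLs, 3) or cytokine induced killer (CIK) cells (2) alone. The lung table held 20 libraries of autochthonous lung tumors of KP mice treated with inhaled TRI-IT (9), subcutaneous TRI-IT (7) or anti-PD1 alone (4). The arms table held subcutaneous B16F10 tumors after no treatment (control, 5), TRI-IT (10), triple (5), anti-PD1 + TLR mix (10), TLR mix + ACT (6), anti-PD1 (6), TLR mix (3) and ACT (4). It also held subcutaneous KP lung tumor cells as control (18), TRI-IT (10), triple (7), anti-PD1 + TLR mix (9), TLR mix + ACT (7), anti-PD1 (4), TLR mix (4), ACT (5) and lymphodepletion alone (5).

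Depth per library was 6.62 to 8.86 M reads after combined ACT, 4.04 to 9.005 after gamma-delta T cells, 6.07 to 8.52 after LAK cells, 3.77 to 7.55 after CTLs and 3.50 to 6.02 after CIK cells. Lung libraries held 2.58 to 6.17 M reads (inhaled), 1.98 to 4.79 (subcutaneous) and 2.91 to 4.23 (anti-PD1). Libraries of the arms table spanned 0.108 to 14.7 M reads, with the shallowest among B16 anti-PD1 + TLR mix. Levels are normalized reads per library (mean ± SD), fold changes are log2 ± SE, and adjusted p-values are limma's.

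The first comparison asks how B16F10 tumors given the combined cells differed from tumors given gamma-delta T cells alone. Genes that rose after combined ACT included interferon-induced genes and single genes of macrophages. Oasl2 (chromosome 5, 114896936 to 114912234), an antiviral gene induced by interferon, rose by 1.93 ± 0.34, from 54.3 ± 16.3 (n = 8) to 240.4 ± 164 normalized reads (n = 4; adjusted p = 0.0222). Hk3 (chromosome 13, 55005985 to 55021385), the hexokinase of myeloid cells, rose by 2.80 ± 0.53, from 9.73 ± 7.59 to 64.2 ± 29.96 (adjusted p = 0.0237). Both stood above every gamma-delta library in 4 of 4 combined ACT libraries. Cyclin B1, which drives entry into mitosis (Ccnb1, chromosome 13, 100778650 to 100786570), fell by 0.53 ± 0.12 to 411 ± 32.1 from 599.6 ± 81.1 split reads (adjusted p = 0.0416) and lay below every gamma-delta library in all 4. Of 28871 genes, 98 passed as higher and 13 as lower, while 4317 had an unadjusted p under 0.05.

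Of the type I interferon list, 7 of 20 members rose and 13 did not pass; adjusted over the list alone, 19 rose. They included Stat2 (1.19 ± 0.20, adjusted p = 0.0222), part of the complex that carries the type I interferon signal, the RNA sensor gene Ddx58 (1.04 ± 0.19, adjusted p = 0.0222), both on split reads, and Ifit3 (1.73 ± 0.30, adjusted p = 0.0229). Its camera test gave an adjusted p = 1.58e-17 with the preset correlation and an adjusted p = 0.244 with an estimated correlation. Of the interferon-gamma list 3 of 18 rose, 16 when adjusted over the list alone (camera 1.32e-14, adjusted p = 0.311 with an estimated correlation). Irf1 (chromosome 11, 53770014 to 53778374), an interferon-induced transcription factor gene, rose by 1.25 ± 0.25 (adjusted p = 0.0369). It rests on split reads and stood above all gamma-delta libraries in 3 of 4. Other named rises were Slfn8 (2.80 ± 0.56), Gbp5 (2.41 ± 0.50, from 20.5 ± 12.6 to 117.7 ± 88.1), Ifit3b (2.09 ± 0.37) and Irgm2 (2.07 ± 0.42), with adjusted p of 0.0353, 0.0357, 0.0263 and 0.0356. Cxcl9, a chemokine that draws T cells, was at 774 ± 540.3 against 207 ± 98.1 and did not pass (adjusted p = 0.108).

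Of the macrophage list 1 of 15 rose, 12 when adjusted over the list alone (camera 9.61e-09, adjusted p = 0.347 with an estimated correlation). That member was Cd68 (chromosome 11, 69664213 to 69666153), a lysosomal protein of macrophages, at 433 ± 186 against 128 ± 54.7 (1.73 ± 0.37, adjusted p = 0.049). Further rises were Dram1, a lysosomal regulator of autophagy (2.73 ± 0.50, adjusted p = 0.0222), the monocyte chemokine Ccl12 (2.62 ± 0.55, adjusted p = 0.0347) and Calhm6 (2.44 ± 0.56, adjusted p = 0.0498). Of the TLR and NF-kB list 1 of 20 rose, Nfkbia, the inhibitor of NF-kB (0.73 ± 0.16, adjusted p = 0.0433), and 4 when adjusted over the list alone (camera 0.000325, adjusted p = 0.347 with an estimated correlation). No member of MHC class I passed over all genes, against 10 of 13 adjusted over the list alone (camera 1.02e-06, adjusted p = 0.347 with an estimated correlation). The same holds for MHC class II (3 of 9; camera 0.000362, estimated 0.416) and alternative macrophage activation (4 of 13; 0.000381, 0.347). No member passed over all genes in fibroblast and matrix (4 of 15 alone; camera 2.73e-06, estimated 0.416) or dendritic cell (0 of 12 alone; 0.014, 0.347). Of the cell cycle list 1 of 20 fell, 5 when adjusted over the list alone (camera 3.26e-08, adjusted p = 0.347 with an estimated correlation). Ccnb1 was that member, and the kinesin gene Kif22 fell by 0.61 ± 0.13 (adjusted p = 0.0357).

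Other named falls were Slc25a47 (-1.46 ± 0.33, 5.09 ± 2.29 against 15.3 ± 3.49, adjusted p = 0.0449), Fbxw4 (-1.17 ± 0.23, split reads, adjusted p = 0.0245), Syde2 (-1.001 ± 0.19, adjusted p = 0.0229) and the linker histone gene H1f0 (-0.66 ± 0.14, adjusted p = 0.0357). A pair of lipid synthesis genes fell as well, Scd2 by 0.65 ± 0.11 (adjusted p = 0.0222) and Fdps by 0.61 ± 0.12 (adjusted p = 0.027), both on split reads. The T cell list had no member passing of 16, nor did CD8 and cytotoxic effector (16) or gamma-delta T cell (9), with camera adjusted p of 0.153, 0.194 and 0.389. Cd3e, part of the T cell receptor complex, was at 27.4 ± 39.5 against 18.9 ± 25.9 (adjusted p = 0.761). Adjusted over the list alone, 1 member rose in NK cell (12 tested, camera 0.153), regulatory T cell (7, 0.286), general epithelium (10, 0.0209, estimated 0.416) and lung alveolar epithelium (12, 0.996), and 3 in the immediate early list (12, 0.152). No member passed in B and plasma cell, checkpoint, neutrophil, melanocyte, airway, endothelium, keratinocyte, muscle, adipocyte, red blood cell, hypoxia and mitochondrially encoded lists (lowest camera value 0.0109 for hypoxia, 0.549 with an estimated correlation).

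The count rests on few libraries. Without combined ACT replicates 1, 3 and 4 it was 6, 7 and 20, ending 23, 22 and 16 of the 23 named calls, and without replicate 2 it was 412 and ended 0. Gamma-delta libraries 5 to 8 lay at -80.8 to -70.6 on the first principal component of the transfer table (39.2% of variance), against 1.33 to 36.3 for all other libraries. Without these 4, 1 gene passed, none of the 23 named calls held, and no list member passed over all genes; adjusted over the list alone 17 type I interferon, 10 interferon-gamma and 2 macrophage members rose, and 4 cell cycle members fell. In that adjustment MHC class I, MHC class II and fibroblast and matrix then had 0 members passing by limma, TLR and NF-kB and the immediate early list 2 each, and alternative macrophage activation 1. The 23 named genes kept their direction under every alternative. Over 12 alternatives the fold change was 1.53 to 2.31 for Oasl2, 0.976 to 1.39 for Stat2, 2.07 to 3.22 for Hk3 and -0.587 to -0.430 for Ccnb1. A fit on the 2 groups alone called 5 genes, limma-voom 525 (397 higher, 128 lower), and quantile normalization 121 (64 higher, 57 lower), moving the median fold change of all genes from 0.08 to -0.05.

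Against LAK cells alone, 6 of the 28 genes that rose after combined ACT belong to the interferon-gamma list. Gbp5 (chromosome 3, 142493978 to 142522344), a guanylate-binding protein of the interferon-gamma response, rose by 3.02 ± 0.57, from 11.6 ± 4.75 (n = 4) to 117.7 ± 88.1 normalized reads (n = 4; adjusted p = 0.035). Nlrc5 (chromosome 8, 94434356 to 94527272), the activator of MHC class I genes, rose by 1.97 ± 0.36, from 38.3 ± 12.8 to 156 ± 58.4 (adjusted p = 0.0287). The 10 named calls were all higher in 4 of 4 combined ACT libraries than in every LAK library. Of 28871 genes 30 passed, 28 higher and 2 lower, and 1505 had an unadjusted p under 0.05.

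Of the interferon-gamma list 6 of 18 members rose, and 16 when adjusted over the list alone (camera 1.29e-36, adjusted p = 0.0176 with an estimated correlation). Irf1 rose by 1.80 ± 0.29 (adjusted p = 0.0194), from 325 ± 22.7 to 1224 ± 534 split reads. Gbp6 rose by 3.44 ± 0.53 (adjusted p = 0.0174) and the immunity-related GTPase gene Iigp1 by 3.22 ± 0.56 (adjusted p = 0.0349). Of the type I interferon list 2 of 20 rose, 15 when adjusted over the list alone (camera 2.17e-27, adjusted p = 0.0176 with an estimated correlation). Stat2 rose by 1.59 ± 0.23 (chromosome 10, 128270559 to 128292849; adjusted p = 0.00322). Of MHC class I genes 1 of 13 rose, 12 when adjusted over the list alone (camera 5.41e-25, adjusted p = 0.0176 with an estimated correlation). H2-K1, a classical class I gene, was at 3901 ± 2029 against 1299.6 ± 422 split reads and did not pass (adjusted p = 0.309). Serpina3g (2.696 ± 0.52, adjusted p = 0.0331), Batf2 (2.28 ± 0.46, adjusted p = 0.0432), Oas2 (2.22 ± 0.41, adjusted p = 0.0287) and Oasl2 (2.08 ± 0.39, adjusted p = 0.0349) complete the named rises. Igtp, at 947 ± 819 against 93.03 ± 30.6 split reads (adjusted p = 0.0704), and Cxcl9, at 774 ± 540.3 against 86.3 ± 26.3 (adjusted p = 0.0553), did not pass.

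Lists of immune cells had no member passing over all genes against LAK cells. Camera called T cell (2.46e-05), CD8 and cytotoxic effector (1.1e-05), macrophage (2.46e-05) and MHC class II (2.36e-05) higher, with adjusted p of 0.394, 0.357, 0.394 and 0.357 with an estimated correlation. Cd8a was at 24.7 ± 44.9 against 2.94 ± 2.30 (adjusted p = 1) and Klrk1, an activating receptor of killer cells, at 62.1 ± 27.1 against 27.004 ± 8.22 (adjusted p = 0.556). Camera called cell cycle (0.00196), hypoxia (0.00196) and mitochondrially encoded genes (0.00665) lower, with adjusted p of 0.464, 0.394 and 0.357 with an estimated correlation. Without combined ACT replicates 1, 2 and 3 the count was 4, 79 and 4, and without LAK replicates 1, 2, 3 and 4 it was 5, 8, 13 and 13. These ended 9, 0, 9, 9, 9, 8 and 6 of the 10 named calls, and leaving out combined ACT replicate 4 ended 2. The fold changes of all 10 kept their direction under every alternative. Leaving out gamma-delta libraries 5 to 8, which share the fit, gave 28 genes and ended 4 of the 10 named calls. Members passing over all genes were then 5 for interferon-gamma, 3 for MHC class I and 1 for type I interferon, with adjusted p of 0.0326, 0.0326 and 0.0591 with an estimated correlation, so the type I interferon call was lost. A fit on the 2 groups alone called 13 genes and limma-voom 16, of which 13 were higher and 3 lower.

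Against CTLs alone, 4 of 28871 genes passed (1 higher, 3 lower; 1581 at an unadjusted p under 0.05), all predicted genes named after their values were seen. The pseudogene Gm20768 (chromosome 5, 137186830 to 137189167) fell by 1.36 ± 0.19, at 1165 ± 241 (n = 4) against 2951 ± 399 normalized reads (n = 3; adjusted p = 0.0086). The other calls sat near the floor. Gm7429 was at 3.89 ± 0.898 split reads against 0 in every CTL library. Gm13413 (split reads) and Gm22145 were at 0 in every combined ACT library against 4.26 ± 2.31 and 3.77 ± 2.51. Immune genes did not pass. Cathepsin S (Ctss) was at 2933 ± 1694 against 1018 ± 720.5 (adjusted p = 0.944), the lysozyme gene Lyz2 at 1666 ± 874 against 782 ± 536 split reads (adjusted p = 0.948) and the interferon-induced Usp18 at 1661 ± 757 against 1121 ± 381 (adjusted p = 0.963). No list had a member passing; camera called type I interferon (3.37e-07), macrophage (2.03e-06) and fibroblast (4.66e-06) higher and cell cycle (1.98e-06) lower, each with an adjusted p = 0.465 with an estimated correlation. It also called immediate early and alternative macrophage activation (0.00307 each), TLR and NF-kB (0.00739), MHC class II (0.0082), B and plasma cell (0.0168), neutrophil (0.0172), T cell and dendritic cell (0.0401 each) and keratinocyte (0.049) higher, with 0.465 to 0.639 with an estimated correlation. The count was 1 without combined ACT replicate 3 or 4 and 7 without CTL replicate 2, and limma-voom called 0 (2013 at an unadjusted p under 0.05). Quantile normalization called 3 lower and 0 higher.

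Against CIK cells alone, with 2 libraries, 1 of 28871 genes passed and 1690 had an unadjusted p under 0.05. Gm2026 (chromosome 2, 175965331 to 175980303) rose by 4.33 ± 0.50 (n = 4 against 2, adjusted p = 0.000213); its read unit could not be recovered, and it was named after its value was seen. Interferon genes lay higher without passing. Usp18 was at 1661 ± 757 against 526 ± 89.2 (adjusted p = 0.591) and Irf1 at 1224 ± 534 against 499.8 ± 86.5 (adjusted p = 0.521), each above both CIK libraries in 4 of 4. Adjusted over the list alone, 12 of 20 type I interferon members rose (camera 4.92e-20, adjusted p = 0.157 with an estimated correlation) and 8 of 18 interferon-gamma members (1.03e-13, 0.366). Camera also called fibroblast and matrix (2.06e-05), MHC class I (4.71e-05), macrophage (0.0071), and MHC class II, NK cell and TLR and NF-kB (0.0492 each) higher and cell cycle lower (2.43e-05), each with an adjusted p = 0.702 with an estimated correlation. The count was 252 and 358 without CIK replicates 1 and 2, where the lone library is assumed to vary like the other groups, and 10 and 2 without combined ACT replicates 2 and 3. Limma-voom called 0 (1798 at an unadjusted p under 0.05), and quantile normalization 2 higher and 2 lower. None of these 4 comparisons tests whether the responses to the single cell types differ.

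**Figure D1:**
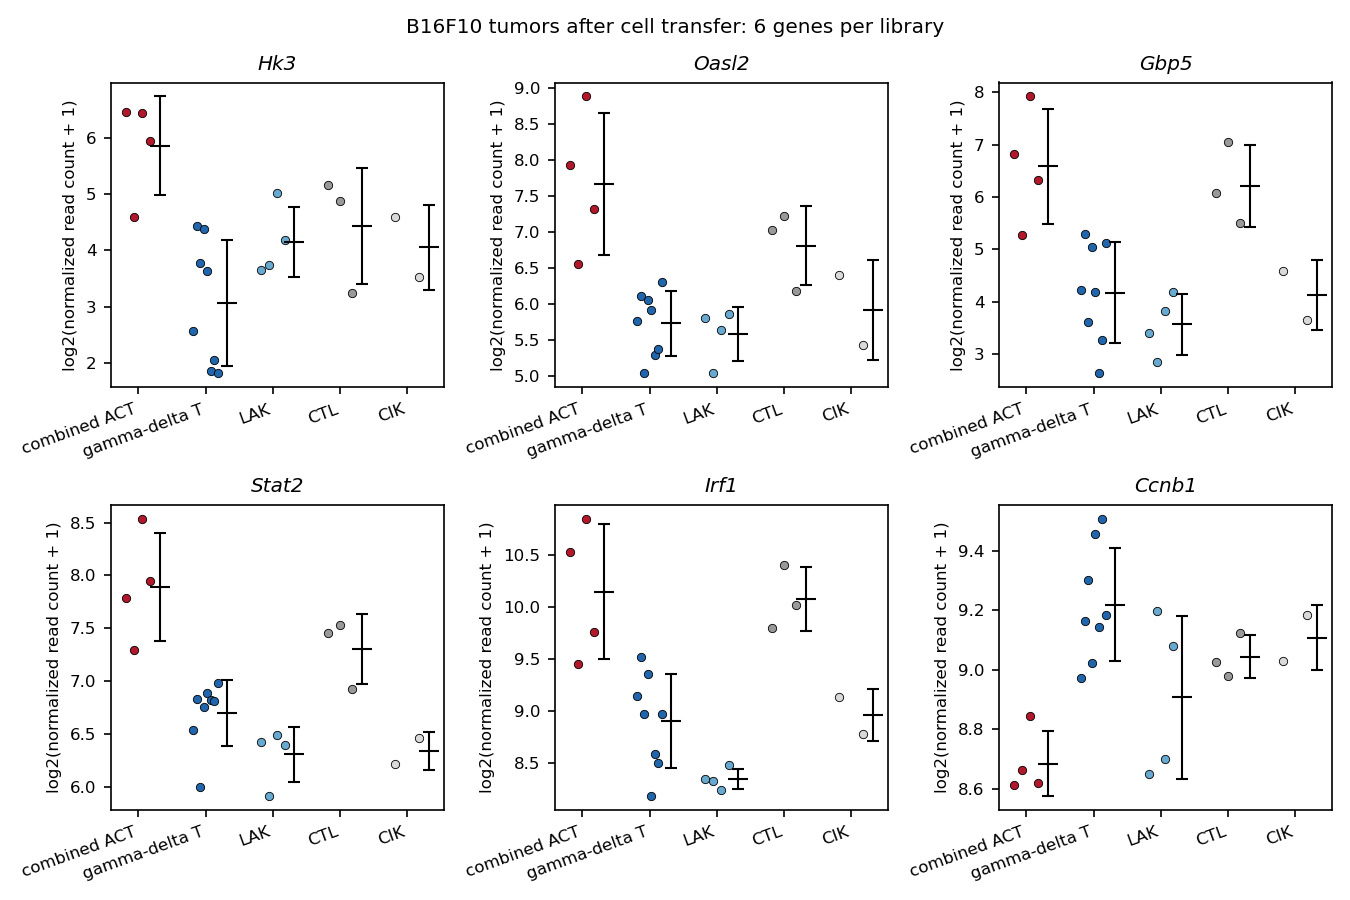
Values of 6 genes in each of the 21 libraries of the transfer table, by transferred cells; the y axis is log2(normalized read count + 1), points are libraries, and the bar beside them is the mean ± SD of the log values. Hk3 and Oasl2 lie higher in the 4 combined ACT libraries than in all 8 gamma-delta libraries, and Gbp5, Stat2 and Irf1 higher than in all 4 LAK libraries, while Ccnb1 lies lower than in all 8 gamma-delta libraries.

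In lung tumors, inhaled TRI-IT was compared with anti-PD1 alone. Passing members of the interferon, checkpoint and macrophage lists were higher with inhaled TRI-IT, and 7 of the 8 passing melanocyte members lower. Oasl2 (chromosome 5, 114896936 to 114912234), an antiviral gene induced by interferon, rose by 2.63 ± 0.55, from 32.9 ± 3.77 (n = 4) to 285 ± 254 normalized reads (n = 9; adjusted p = 0.00125). Cd274 (chromosome 19, 29367455 to 29388095), which encodes the PD1 ligand, rose by 1.97 ± 0.50, from 73.3 ± 12.4 to 394 ± 383 (adjusted p = 0.00569), and Pdcd1 (chromosome 1, 94038305 to 94052553), which encodes PD1, by 2.52 ± 0.71, from 1.25 ± 0.414 to 22.006 ± 33.1 (adjusted p = 0.0115). These 3 genes stood above every anti-PD1 library in 9 of 9 inhaled libraries. In all, 4052 of 16117 genes passed, 1969 higher and 2083 lower. Every inhaled library also stood apart from the rest of the table, at 41.9 to 64.2 on a first principal component with 55.2% of the variance, against -54.0 to -34.3 in the other 11 libraries, and this separation goes with each gene group below.

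Of the interferon-gamma list 6 of 9 members rose, 7 when adjusted over the list alone (camera 0.00385, adjusted p = 0.808 with an estimated correlation, fry 0.0384). Gbp2 (chromosome 3, 142620602 to 142638008) rose by 2.83 ± 0.68 on split reads (adjusted p = 0.00458), and the chemokine genes Cxcl9 by 3.10 ± 0.81, from 45.8 ± 24.2 to 689 ± 775 (adjusted p = 0.00835), and Cxcl10 by 3.74 ± 0.92 on split reads (adjusted p = 0.00511), each in 8 of 9 libraries. Of the type I interferon list 7 of 13 rose, 8 when adjusted over the list alone (camera 0.00343, adjusted p = 0.808 with an estimated correlation, fry 0.0454). Beside Oasl2, Cmpk2 (2.45 ± 0.55, adjusted p = 0.00226) and Ifi44 (2.05 ± 0.51, adjusted p = 0.00555) rose in 9 of 9, and Oas3 by 4.18 ± 0.65 (adjusted p = 5.48e-05). Isg15, another member, was at 202 ± 272 against 78.2 ± 17.4 and did not pass (adjusted p = 0.781). Ubiquitin D (Ubd, 3.45 ± 0.97, adjusted p = 0.0125) and Ly6i (3.60 ± 0.84, split reads, adjusted p = 0.00359) were further large rises.

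Of the T cell list 3 of 15 rose, 3 when adjusted over the list alone (camera 0.0299, adjusted p = 0.89 with an estimated correlation). Cd5 rose by 2.99 ± 0.69, from 0.571 ± 0.659 to 15.3 ± 12.1 (adjusted p = 0.00256), and the receptor constant region Trbc2 by 2.11 ± 0.54 on split reads (adjusted p = 0.00636), while Cd3e was at 24.998 ± 35.7 against 7.61 ± 2.72 (adjusted p = 0.486). The killer cell receptor gene Klrc1 rose by 3.76 ± 0.68 on split reads (adjusted p = 0.000319). Of the checkpoint list 3 of 6 rose, 4 when adjusted over the list alone (camera 0.0576, adjusted p = 0.808 with an estimated correlation, fry 0.0208). CD8 and cytotoxic effector (10 tested), gamma-delta T cell (8) and regulatory T cell (5) had 1 rise each, and NK cell (5) and B and plasma cell (11) 0 by limma. Of the macrophage list 6 of 13 rose, 7 when adjusted over the list alone (camera 0.0161, adjusted p = 0.808 with an estimated correlation, fry 0.0435). C1qc (chromosome 4, 136889804 to 136893065), a complement gene of tissue macrophages, rose by 1.88 ± 0.41, from 121 ± 16.5 to 566 ± 440.3 (adjusted p = 0.00162), and Mertk, a receptor for dying cells, by 1.27 ± 0.30 (adjusted p = 0.00305). Of 18 TLR and NF-kB members 3 rose and 1 fell, with Tnf at 22.1 ± 16.3 against 1.17 ± 1.09 (3.33 ± 0.63, adjusted p = 0.000415). Neutrophil (9) and dendritic cell (7) had 2 rises each, and endothelium 3 of 9 (camera 0.0299, adjusted p = 0.844 with an estimated correlation).

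Antigen presentation genes went both ways, and inhaled libraries stood apart here too. Cd74 (chromosome 18, 60803848 to 60812652), the invariant chain of MHC class II, fell by 3.30 ± 0.38, to 559 ± 253 from 5023 ± 1757 (adjusted p = 8.98e-07), and the peptide transporter gene Tap2 (chromosome 17, 34203527 to 34216321) by 2.78 ± 0.38 on split reads (adjusted p = 9.89e-06), each in 9 of 9 libraries. Psmb10, an immunoproteasome gene, rose by 1.04 ± 0.26, from 237 ± 32.1 to 511 ± 188 (adjusted p = 0.00545). MHC class I had 3 rises and 1 fall of 6, and MHC class II 1 and 1 of 4. Of the melanocyte list 1 rose and 7 of 9 fell (camera 0.00315, adjusted p = 0.239 with an estimated correlation, fry 2.83e-06). Dct (chromosome 14, 118012790 to 118052244) fell by 5.83 ± 0.49 on split reads (adjusted p = 3.85e-09), Pmel by 2.98 ± 0.51 on split reads (adjusted p = 0.000144) and Mlana by 1.82 ± 0.60 (adjusted p = 0.0295), while Mitf, a transcription factor also used outside melanocytes, rose by 1.302 ± 0.33 (adjusted p = 0.00513). Of the cell cycle list 4 of 18 fell (camera 0.077, adjusted p = 0.89 with an estimated correlation), among them Aurkb (chromosome 11, 69045647 to 69051664), a mitotic kinase, at 3.71 ± 2.73 against 21.2 ± 8.68 (-2.41 ± 0.54, adjusted p = 0.00201), and Cdc20 (-1.70 ± 0.43, adjusted p = 0.00537). Alveolar epithelium had 2 rises and 4 falls of 10, with Etv5 at 1484 ± 510.5 against 505 ± 211 (1.51 ± 0.42, adjusted p = 0.0104) and Ager at -1.73 ± 0.51 (adjusted p = 0.0148).

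In the remaining lists, immediate early genes had 1 rise and 2 falls of 5, alternative macrophage activation 1 and 1 of 10, muscle 2 falls of 7, and general epithelium (6), keratinocyte (3), adipocyte (7) and hypoxia (9) 1 fall each. Airway (5) and fibroblast (15) had 0 by limma, and for red blood cell and mitochondrially encoded genes fewer than 3 members could be tested. Steep changes also fell on noncoding genes and genes of uncertain unit. Rpph1, the RNA of ribonuclease P (-7.08 ± 0.76, adjusted p = 4.47e-07), the host gene Snhg6 (-6.35 ± 0.45, adjusted p = 2.03e-10), Mir703 (-5.33 ± 0.50, adjusted p = 2.9e-08) and Rian (-4.59 ± 0.98, adjusted p = 0.00178) fell. Bc1 (5.46 ± 0.37, adjusted p = 1.23e-10), a small cytoplasmic RNA, and Atg9a (3.32 ± 0.78, adjusted p = 0.00338) rose, both on split reads, as did Usp50 (3.86 ± 0.30, adjusted p = 1.05e-09), whose read unit is unknown. Falls among coding genes were Rorb (-6.45 ± 0.57, adjusted p = 1.45e-08), the stress gene Hmox1 (chromosome 8, 75093621 to 75100589; 2.38 ± 4.44 against 134 ± 53.3, adjusted p = 1.12e-08), Cideb (-5.13 ± 1.34, adjusted p = 0.00815) and the albumin gene Alb (-4.88 ± 1.48, adjusted p = 0.0203).

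Passing genes made up 21.7% of 11085 genes in whole reads and 31.4% of 4310 genes in hundredths of a read, and 1775 of 6901 protein-coding genes in whole reads passed on their own (1165 higher, 610 lower). Leaving out anti-PD1 replicate 60 ended the calls of Alb (-4.75) and Mlana (-1.40), replicate 73 those of Alb (-4.10), Mlana (-1.76) and Etv5 (1.24), and replicate 71 or 78 that of Ager (-1.58 and -1.59). The numbers in the titles run from 60 to 83 for the other libraries and lie above 83 for all inhaled ones, so route and number series cannot be told apart. Limma-voom called 1359 higher and 2623 lower, moving the median fold change of all genes from 0.05 to -0.10, and ended the calls of Cxcl10 (3.70, adjusted p = 0.104), Ly6i (3.56, adjusted p = 0.0604) and Ubd (3.45, adjusted p = 0.171), whose fold changes stayed between 3.24 and 4.16 over 11 alternatives each.

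Subcutaneous TRI-IT against anti-PD1 alone gave 3 calls of 16117 genes (1 higher, 2 lower), named after their values were seen, with 1226 at an unadjusted p under 0.05. Dhh (chromosome 15, 98891152 to 98898540), which encodes desert hedgehog, rose by 3.26 ± 0.56, from 0.289 ± 0.577 (n = 4) to 11.8 ± 5.78 split reads (n = 7; adjusted p = 0.0299). The pseudogene Gm16198 and the small nuclear RNA Gm23240 (split reads) were at 0 in all 7 libraries, against 47.4 ± 17.04 and 5.16 ± 1.36. T cell genes lay higher without passing over all genes, with Cd3e at 52.96 ± 41.3 against 7.61 ± 2.72 (adjusted p = 0.426) and Trbc2 at 189.9 ± 138 against 32.5 ± 8.26 split reads (adjusted p = 0.269), each above all anti-PD1 libraries in 7 of 7. The same holds for Fos, at 872 ± 444 against 304 ± 114.9 (adjusted p = 0.316), and for Dnajb1, at 4222 ± 2729 against 1654 ± 614 (adjusted p = 0.305) in 6 of 7.

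Adjusted over the list alone, 6 of 15 T cell members rose (camera 1.29e-07, adjusted p = 0.409 with an estimated correlation), 4 of 13 type I interferon members (1.29e-07, 0.409) and 3 of 9 interferon-gamma members (1.74e-05, 0.409). The same count was 3 of 9 for neutrophil (0.000217, 0.326), 1 of 18 for TLR and NF-kB (0.000146, 0.418), 1 of 10 for CD8 and cytotoxic effector (8.02e-05, 0.409) and 5 of 5 for immediate early genes (6.72e-06, 0.117, fry 0.0178). Camera also called endothelium higher (0.0113, estimated 0.62; 9 of 9 members positive) and B and plasma cell lower (0.0212, estimated 0.686; 0 of 11 positive), with no member passing in either. The interferon gene Rsad2, at 353 ± 221 against 74.9 ± 37.6 (adjusted p = 0.469), and Cxcl9, at 167 ± 106.99 against 45.8 ± 24.2 (adjusted p = 0.686), did not pass. The count was 10 without anti-PD1 replicate 71, and leaving out replicate 60, 73 or 78 ended the call of Dhh (3.17 each time). Quantile normalization called 3 higher and 2 lower and limma-voom 2 and 2.

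Inhaled against subcutaneous TRI-IT is the comparison of routes. Passing members of the immediate early and cell cycle lists were lower in inhaled tumors and those of the macrophage list higher (4 of 13), while antigen presentation genes went both ways. Fos (chromosome 12, 85473890 to 85477273), an immediate early transcription factor gene, fell by 3.33 ± 0.32, to 87.6 ± 46.4 (n = 9) from 872 ± 444 normalized reads (n = 7; adjusted p = 4.6e-08), and the heat shock gene Dnajb1 (chromosome 8, 83608193 to 83612653) by 3.09 ± 0.27, to 438 ± 89.1 from 4222 ± 2729 (adjusted p = 4.36e-09), each in 9 of 9 libraries. In all, 4103 of 16117 genes passed, 1734 higher and 2369 lower. The separation of the inhaled libraries on the first principal component goes with these groups as well.

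Of the immediate early list 4 of 5 fell (camera 0.00914, adjusted p = 0.507 with an estimated correlation, fry 7.04e-06), and of the cell cycle list 9 of 18, 10 when adjusted over the list alone (camera 0.00914, adjusted p = 0.969 with an estimated correlation). Aurkb fell by 2.34 ± 0.45 (adjusted p = 0.000446) and Cdc20 by 1.62 ± 0.36 (adjusted p = 0.00174). MHC class I had 2 rises and 1 fall of 6, and MHC class II 2 and 1 of 4. Cd74 fell by 3.07 ± 0.32, to 559 ± 253 from 4222 ± 1029 (adjusted p = 1.28e-07), and Tap2 by 3.46 ± 0.32 on split reads (adjusted p = 1.76e-08). Of the T cell list Trac fell by 1.81 ± 0.54 (adjusted p = 0.0154) and Cd3e by 1.68 ± 0.60 (adjusted p = 0.0445), 2 of 15 members (1 when adjusted over the list alone), while 7 of 15 had a positive fold change and the list did not pass (camera 0.854). Of the macrophage list 4 of 13 rose, while 5 rose and 2 fell when adjusted over the list alone (camera 0.126), and 2 of 10 alternative macrophage activation members fell. C1qc rose by 1.496 ± 0.34 (adjusted p = 0.00236). Pdcd1 rose by 1.79 ± 0.60 (adjusted p = 0.03) and Cd274 by 1.25 ± 0.42, from 133 ± 56.6 to 394 ± 383 (adjusted p = 0.0305). TLR and NF-kB had 4 falls of 18 (camera 0.704), type I interferon 2 rises and 1 fall of 13 (0.609) and interferon-gamma 1 rise of 9 (0.355). Of the melanocyte list 5 of 9 fell and 1 rose (camera 0.00914, adjusted p = 0.507 with an estimated correlation, fry 5.76e-06), with Dct at -5.37 ± 0.41 (adjusted p = 6.02e-10) and Pmel at -2.81 ± 0.43 (adjusted p = 3.02e-05), both on split reads. The neutrophil granule gene Ngp (-5.17 ± 0.83, adjusted p = 8.17e-05) and the heme synthesis gene Alas2 of red cells (-3.44 ± 0.65, split reads, adjusted p = 0.000487) fell too. In the remaining lists, alveolar epithelium had 3 rises and 3 falls of 10, checkpoint 2 rises of 6, and gamma-delta T cell (8), B and plasma cell (11), dendritic cell (7) and endothelium (9) 1 rise each. Neutrophil (9), fibroblast (15), muscle (7, fry 0.0355) and hypoxia (9) had 2 falls each, and CD8 and cytotoxic effector (10), general epithelium (6), keratinocyte (3) and adipocyte (7) 1 fall each, with camera values of 0.345 or more for all these lists.

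Large changes were again those of Bc1 (6.55 ± 0.31), Usp50 (4.17 ± 0.25), Rpph1 (-6.71 ± 0.64), Hmox1 (-6.52 ± 0.44) and Rorb (-6.51 ± 0.48), with adjusted p of 1.3e-13, 8.68e-12, 4.97e-08, 6.14e-11 and 5.37e-10, and Atg9a rose by 3.23 ± 0.66 (adjusted p = 0.000862). Of protein-coding genes in whole reads, 1659 of 6901 passed on their own (953 higher, 706 lower). The calls of Cd3e (adjusted p = 0.0674) and Pdcd1 (adjusted p = 0.0504) were lost with only the groups compared in the fit, and that of Cd3e without a filter on low values too. Their fold changes stayed, at -1.82 to -1.50 for Cd3e and 1.79 to 2.45 for Pdcd1 over the alternatives. The route and the number series in the titles coincide here as well. Limma-voom moved the median fold change of all genes from -0.02 to -0.15, with 1419 higher and 2929 lower.

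**Figure D2:**
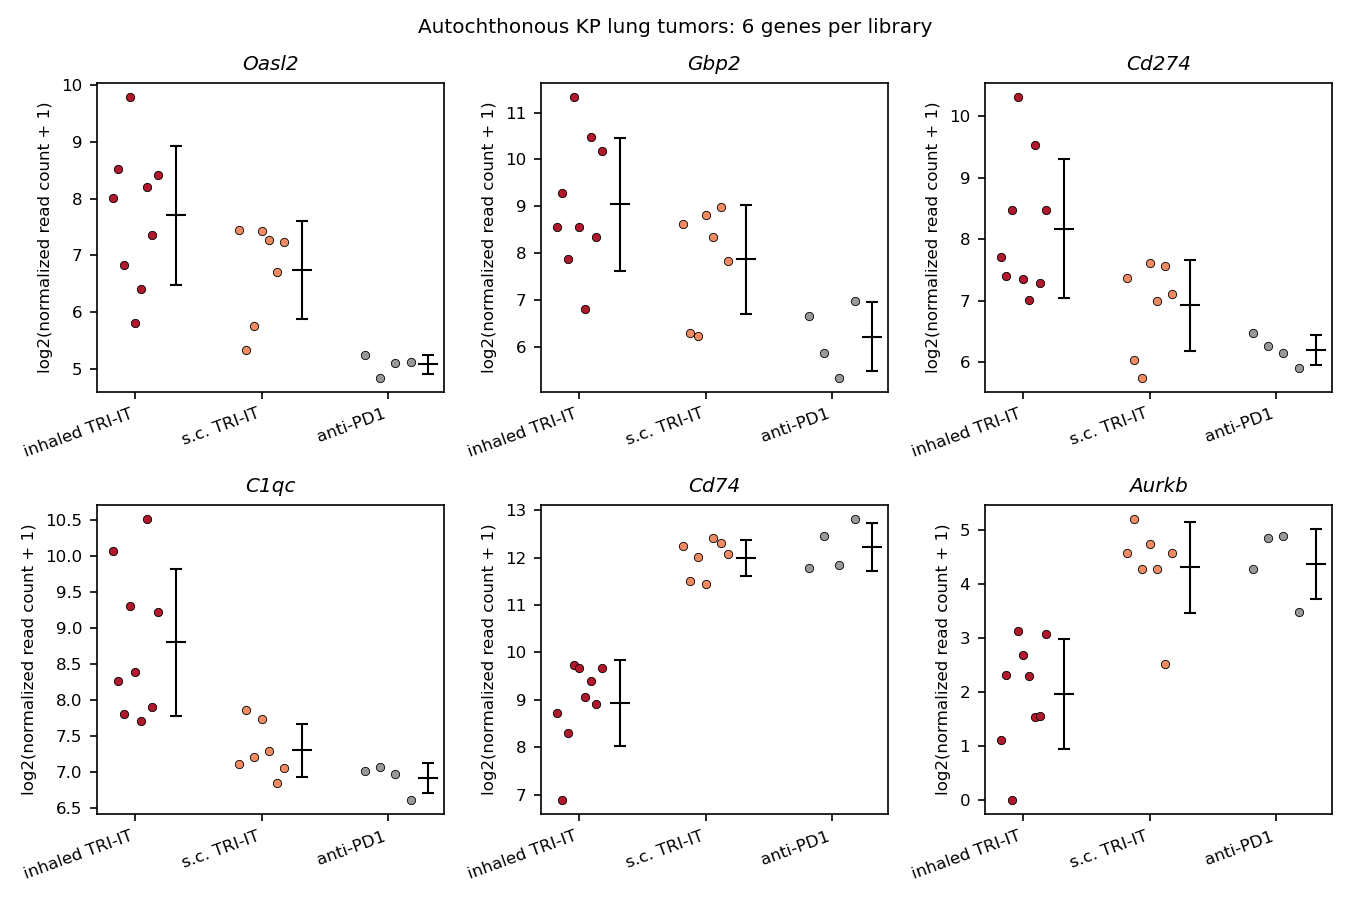
Values of 6 genes in each of the 20 libraries of the lung table, by treatment; the y axis is log2(normalized read count + 1), points are libraries, and the bar beside them is the mean ± SD of the log values. In all 9 inhaled libraries Oasl2, Cd274 and C1qc lie above, and Cd74 and Aurkb below, all 4 anti-PD1 libraries; Gbp2 lies above them in 8.

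In subcutaneous B16F10 tumors, TRI-IT against control changed 24 of 28176 rows (8 higher, 16 lower; 10 against 5 libraries), and the rows carry no gene names. Against the same controls, triple called 3 rows (3 higher), anti-PD1 + TLR mix 43 (12 higher, 31 lower), TLR mix + ACT 53 (22 and 31), TLR mix 19 (18 and 1) and ACT 8 (5 and 3). Anti-PD1 called 0 by limma and 0 by limma-voom, with 972 rows at an unadjusted p under 0.05. In these arms 972 to 3056 rows lay under that value, where chance alone gives 1408.8. TRI-IT had 2 rows lower than triple, 21 lower than anti-PD1 + TLR mix and 2 lower than TLR mix + ACT. With quantile normalization the splits were 17 higher and 8 lower for TRI-IT, 6 and 2 for triple, 148 and 97 for TLR mix + ACT, 9 and 2 for TLR mix, 0 and 2 for ACT, and 43 and 35 for TRI-IT against anti-PD1 + TLR mix. The median fold change of all rows moved with it from 0.17 to -0.01 for triple, from 0.14 to 0.00 for anti-PD1 + TLR mix, from 0.11 to -0.03 for TLR mix, from 0.10 to -0.07 for ACT and from -0.22 to -0.01 for TRI-IT against triple. Limma-voom called 7 higher and 4 lower for anti-PD1 + TLR mix and 11 and 8 for TLR mix. With only the groups compared in the fit, limma called 0 rows for TRI-IT, triple, anti-PD1 + TLR mix and TLR mix (781, 1482, 1151 and 1578 at an unadjusted p under 0.05), against 21, 24, 11 and 19 by limma-voom, and 618 for TLR mix + ACT, 2 for anti-PD1 and 1 for ACT.

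Single B16 libraries moved these counts. TRI-IT, TLR mix and TLR mix + ACT also each held libraries that lay far apart on the first principal component. These were the libraries numbered 5 to 20, at -78.1 to -57.4, against -38.0 or above in all other B16 libraries. No B16 control carries such a number, so treatment and number series cannot be told apart for these libraries of the 3 arms. Without control 3, whose library detected 9433 rows, TRI-IT called 54 rows, triple 16, anti-PD1 + TLR mix 90, TLR mix + ACT 98 and anti-PD1 8. Without control 54 the counts were 25 for anti-PD1 + TLR mix, 29 for TLR mix + ACT, 1 for anti-PD1 and 0 for TLR mix (1816 at an unadjusted p under 0.05, by limma). Without control 52 they were 1 for anti-PD1 and 10 for TLR mix, without control 53 26 for anti-PD1 + TLR mix and 10 for TLR mix, and without control 55 11 for triple and 5 for anti-PD1. Triple called 6, 0 and 0 rows without its libraries 60, 61 and 62 (1395 and 1348 at an unadjusted p under 0.05 for the counts of 0, by limma), TLR mix 62 without its library of the highest number (B16_TLR_117), and ACT 47, 16, 31 and 52 without libraries 56, 57, 58 and 59. TRI-IT against triple gave 5, 1, 6 and 1 without triple 60, 62, 63 and 64. Leaving out the 5 shallow B16 libraries, as planned, turned the balance of TRI-IT, anti-PD1 + TLR mix and TLR mix + ACT from mostly lower to mostly higher rows. TRI-IT then called 708 rows (599 higher), triple 636 (450 higher, 186 lower), anti-PD1 + TLR mix 2323 (1971 and 352), TLR mix + ACT 1965 (1397 and 568), TLR mix 365 (274 and 91), ACT 314 (197 higher) and anti-PD1 20 (16 and 4). TRI-IT then called 2 rows higher and 1 lower against triple, 139 and 762 against anti-PD1 + TLR mix, and 10 and 5 against TLR mix + ACT, so the all-lower picture between arms did not hold. Leaving out control 3 as well, chosen after seeing the data, gave 91 rows for TRI-IT, 251 for triple and 389 for anti-PD1 + TLR mix.

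In subcutaneous KP tumors, TRI-IT against control changed 4224 of 29394 rows, 3146 higher and 1078 lower (10 against 18 libraries). The other arms against the same controls called 451 (triple), 2512 (anti-PD1 + TLR mix), 6761 (TLR mix + ACT), 1129 (anti-PD1), 1755 (TLR mix), 1357 (ACT) and 867 rows (lymphodepletion). Higher and lower rows were 427 and 24, 2055 and 457, 3396 and 3365, 902 and 227, 1581 and 174, 1189 and 168, and 746 and 121, in that order. TRI-IT had 2 rows lower than triple, and 1274 higher and 376 lower than TLR mix + ACT. Against anti-PD1 + TLR mix, limma called 0 rows and limma-voom 0, with 660 at an unadjusted p under 0.05. The TLR mix + ACT libraries lay at -101.1 to -58.4 on the second principal component (15.4% of variance), against -28.3 or above in all other KP libraries. Called fold changes of that arm against control reached 11.8 and -15.7, the widest of the KP arms. Its libraries share no number series with other KP groups, so treatment and series cannot be told apart in its counts. With only the groups compared in the fit the counts against controls were 1384 for TRI-IT (1051 higher, 333 lower), 4 for triple, 3 for anti-PD1 + TLR mix, 3876 for TLR mix + ACT, 123 for anti-PD1, 239 for TLR mix, 5 for ACT and 4 for lymphodepletion. TRI-IT against TLR mix + ACT then gave 3801, and against triple 0 by limma (2267 at an unadjusted p under 0.05) and 0 by limma-voom.

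The KP libraries fall into series of title numbers, and the counts against controls were far lower within the series numbered from 75 up. There TRI-IT called 370 rows, triple 1, anti-PD1 + TLR mix 20, anti-PD1 16, ACT 3, and TLR mix and lymphodepletion 0 (1719 and 1885 at an unadjusted p under 0.05, by limma). With the series as a term in a fit of all libraries the counts were 295 for TRI-IT, 368 for triple, 6 for anti-PD1 + TLR mix, 12 for anti-PD1, 14 for TLR mix, 5 for ACT and 1 for lymphodepletion. The libraries of TLR mix + ACT carry numbers 10 to 16, which no other KP group shares, so neither value exists for that arm. Apart from triple, the other arms share only the series from 75 up with the controls. With the series as a term they are thus compared directly with control in the same libraries as before, which is no separate check. Controls numbered 21 to 33 (10 libraries) and from 75 up (6 libraries) differed from each other in 7692 of 29289 rows.

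With quantile normalization the split for KP TRI-IT was 2222 higher and 1578 lower, for triple 226 and 77, for anti-PD1 + TLR mix 1288 and 784, for TLR mix 795 and 400, for ACT 632 and 299, for lymphodepletion 508 and 194, for TRI-IT against triple 1 and 1, and for TRI-IT against TLR mix + ACT 1004 and 703. The median fold change of all rows moved from 0.14 to -0.01 for triple, from 0.11 to 0.00 for anti-PD1 + TLR mix, from 0.08 to -0.03 for anti-PD1, from 0.20 to -0.05 for TLR mix, from 0.16 to -0.01 for ACT and from 0.12 to -0.01 for lymphodepletion. Limma-voom gave 2843 higher and 2280 lower for TRI-IT, 1950 and 1577 for anti-PD1 + TLR mix, and 4179 and 10454 for TLR mix + ACT. Without 1 library of its own, anti-PD1 called 209, 540, 76 and 89 rows (KP_PD1_106, KP_PD1_107, KP_PD1_112 and KP_PD1_113), and TLR mix 951, 578, 623 and 626 (75, 76, 81 and 82). ACT called 707, 539, 627, 645 and 506 (95, 96, 83, 84 and 85), and lymphodepletion 98, 83, 372, 382 and 541 (88, 89, 94 and the pair of higher number, in that order).

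**Figure D3:**
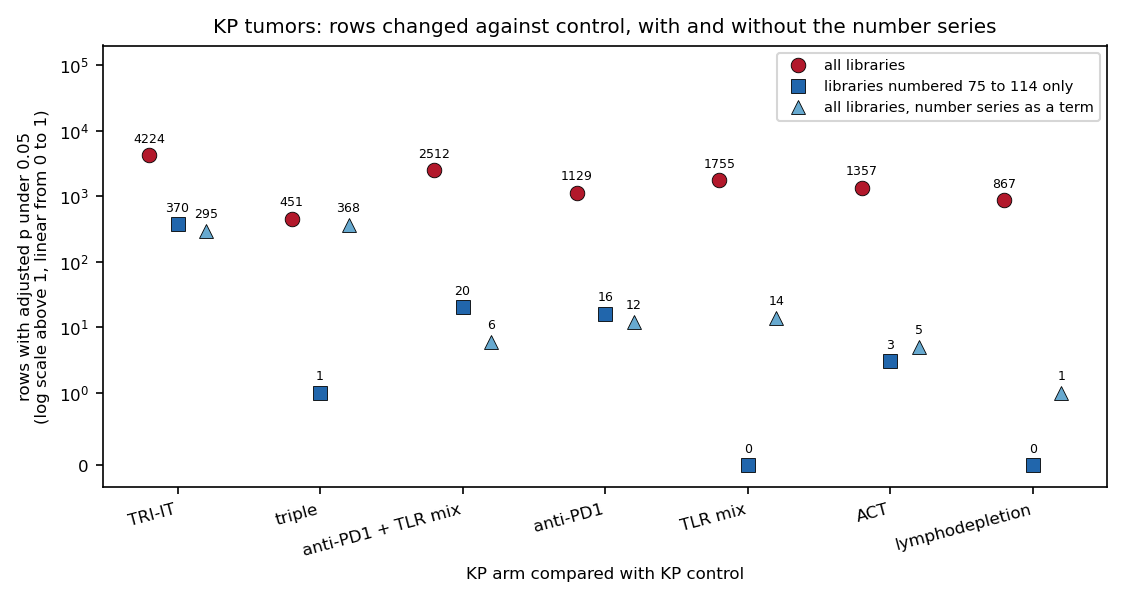
Number of rows with an adjusted p under 0.05 for 7 KP arms against KP control, from all libraries, from libraries numbered from 75 up only, and from all libraries with the number series as a term; the y axis is logarithmic above 1 and linear from 0 to 1. TRI-IT drops from 4224 rows to 370 and 295, and TLR mix from 1755 to 0 and 14. Both settings compare these arms directly with control only in libraries numbered from 75 up, so they are no separate checks.

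The response to TRI-IT was compared between the models directly. The change differed in 219 of 33169 rows, with 64 more positive and 155 more negative in B16 than in KP tumors, and 4706 had an unadjusted p under 0.05. A fit on the groups compared alone called 7 rows, all more negative. Quantile normalization gave 153 and 188, and leaving out the shallow libraries 1848 and 832, which turns the balance. Across 26509 rows tested in both models, which are not independent replicates, the fold changes had a Pearson r of 0.0379 and a Spearman rho of 0.00324. The SD of r over 100 bootstraps of the libraries was 0.108, with a range from -0.231 to 0.230.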

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

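For the results below, the regroupings of samples, the depth test of the KP counts and the cell share test of the lung libraries had their predictions written after the result was seen; the other tests of these patterns had theirs written before. Of the groups of values screened, 9 held 1 library far from the rest of its group, where chance alone would give 5.3.

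The KP counts against controls go with the title numbers. The TRI-IT count of 4224 rows fell to 370 within numbers from 75 up and to 295 with the series as a term, and KP controls numbered 21 to 33 differed from those numbered from 75 up in 7692 rows. TRI-IT and control libraries share only the series from 75 up, so the count of 295 is no separate check. Of 100 random subsets of the same sizes, 13 gave a count no higher than 370 (median 1993, range 0 to 6454). These subsets mix the number series, so they do not show what smaller groups alone would give. The test thus cannot tell a batch from the loss of libraries. The median totals of these 2 sets of controls had a ratio of 1.08, so total depth does not part these sets. Rows detected did not overlap, at 19880 to 22203 for numbers 21 to 33 and 22966 to 24629 from 75 up. Treated libraries were not compared. Shallow controls 1 and 2 (1.36 and 1.37 M reads) are in the count of 4224 but not in that of 370. Leaving out these shallow controls raised the counts of triple, anti-PD1, TLR mix, ACT and lymphodepletion. For these arms that argues against the loss of the shallow controls as a cause of the drop. Depth of the treated libraries stays open as a part of it.

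The inhaled lung libraries stand apart, and their number series coincides with the route. Depth is excluded as the whole cause, since 22.7% of genes still passed between inhaled and subcutaneous TRI-IT after every library was thinned to the shallowest total. Another share of immune or lung cells stays open. Its prediction, that called alveolar genes go 1 way, was not met: 2 rose beside 4 that fell. The rise of Etv5 loses its call without anti-PD1 replicate 73, though its fold change stayed at 1.24. Against subcutaneous TRI-IT the called alveolar genes also went both ways. The test covers a single list, so it does not settle the shares of other cells. A library batch or a different annotation predicted genes that are on in 1 side and off in the other, in both directions. Such genes numbered 19, at 1 or less in every library of one side and at 20 or more in every library of the other. In inhaled libraries 17 were low and 2 high, and each of 99 other splits gave 0. All 19 rest on split reads, so their values are uncertain. None is annotated as protein-coding: they are pseudogenes, antisense, miRNA, snoRNA or unconfirmed genes. Calls over 4 log2 against anti-PD1 made up 2.85% of genes in hundredths of a read and 0.262% of those in whole reads. A batch or annotation difference thus met its prediction, on genes with split reads. A drug effect and another share of cells may be present beside it, and these libraries cannot separate these causes.

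Regrouping the libraries of a pair of groups at random gives the count expected without a treatment effect, where nothing else sets the libraries apart. The shares of splits were not adjusted over the comparisons. For B16 arms against control, the splits with a count as large as the real one, the real one included, were 10 of 100 for TRI-IT (24 real, 2130 highest other), 9 for triple (3, 5), 25 for anti-PD1 + TLR mix (43, 2517), 100 for anti-PD1 (0 by limma and by limma-voom, 972 at an unadjusted p under 0.05; 4), 17 for ACT (8, 20) and 5 of 56 for TLR mix (19, 46). Chance cannot be excluded for these arms in this setting, which holds the shallow libraries. Without those libraries each of these arms called more rows, and no splits were run there. For TLR mix + ACT few splits were as large, at 1 of 100 (53, 2), but this arm shares no number series with the B16 controls, so chance is excluded only if the series has no effect. Between B16 arms, TRI-IT against anti-PD1 + TLR mix gave 1 of 100 (21, 17), which excludes chance by a narrow margin, for this setting alone and only if the number series has no effect, since these arms share no series: the count was 3 without a filter, 9 with a pseudocount of 0.1, 3228 by limma-voom, and 0 by limma with only the groups compared (1168 at an unadjusted p under 0.05). TRI-IT against triple gave 14 (2, 93) and against TLR mix + ACT 14 (2, 25), so chance is not excluded there. The splits of TRI-IT and of anti-PD1 + TLR mix that called 2130 and 2517 rows point to a structure of the B16 samples other than the treatment. TRI-IT libraries 7 to 9 belong to the numbers that stand apart on the first principal component and hold no control, while anti-PD1 + TLR mix has no such library.

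For KP arms against control, few splits were as large for TRI-IT, at 2 of 100 (4224 real, 6099 highest other), anti-PD1 + TLR mix, at 2 (2512, 5484), and TLR mix + ACT, at 1 (6761, 4033). These splits ignore the number series, so they exclude chance only if the series has no effect, and with the series as a term TRI-IT called 295 rows and anti-PD1 + TLR mix 6, and with only the groups compared 1384 and 3, while TLR mix + ACT shares no series with the controls. Chance is not excluded by these splits for triple, at 18 (451, 4718), anti-PD1, at 19 (1129, 8621), TLR mix, at 16 (1755, 8438), ACT, at 9 (1357, 6714), and lymphodepletion, at 12 (867, 6671). Splits that call several times the real count point to a structure of the KP samples, and splits that mix the series also raise the counts these arms are held against. With the series as a term triple called 368 rows, for which no splits were run. Between KP arms, TRI-IT against TLR mix + ACT gave 1 of 100 (1650, 770), with the same limit, and TRI-IT against triple gave 7 (2, 13) and against anti-PD1 + TLR mix 100 (0 by limma and by limma-voom, 660 at an unadjusted p under 0.05; 666).

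For the transfer table, chance is excluded for combined ACT against gamma-delta T cells in this setting alone, at 1 of 100 splits (98 higher and 13 lower real, 17 highest other), since 1 gene passed without gamma-delta libraries 5 to 8, 1 with the replicate number as a block and 5 with only the groups compared. Against LAK cells chance is excluded in this setting alone, at 1 of 35 (30, 1), the lowest share that these splits allow. There the count was 4 without combined ACT replicate 1 or 3, 5 without LAK replicate 1, and 13 with the block or only the groups compared. It was 16 by limma-voom and 0 by limma on the scores as deposited (2090 at an unadjusted p under 0.05). Chance is not excluded against CTLs, at 2 of 35 (4, 13). The CIK comparison, with 2 libraries, had no such test. For lung tumors, chance is excluded for inhaled TRI-IT against anti-PD1, at 1 of 100 (4052, 249), and against subcutaneous TRI-IT, at 1 of 100 (4103, 2806), though these splits cannot part route from number series. It is not excluded for subcutaneous TRI-IT against anti-PD1, at 20 (3, 29).

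The change with TRI-IT differed between B16 and KP tumors in 219 rows, and 7 of 50 splits gave as many (highest other 4337), so chance is not excluded, and a split of that size points to a structure of the samples. In each group that follows, 1 library lay far from the rest of its group, the distance being the share of the group's range that parts it from its nearest neighbor. The library KP_Triple_103 held 10.01 M reads, with the next at 6.19 (0.675). B16 control 3 detected 9433 rows, with the next at 18257 (0.730). B16 TRI-IT 4 detected 5812 rows, with the next at 19900 (0.854). Cd274 in combined ACT replicate 2 was at 5.65 on the log2 scale, with the next at 7.28 (0.832). Prf1 in gamma-delta replicate 3 was at 0, with the next at 2.19 (0.614). Sftpc in gamma-delta replicate 2 was at 0.99 and at 0 in the others (1). Ifng in LAK replicate 2 was at 1.87 and at 0 in the others (1). Sftpc in the inhaled library KP-125 was at 5.78, with the next at 9.11 (0.684). Arg1 in lung anti-PD1 78 was at 5.34, with the next at 7.55 (0.890).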

How the results depend on the processing

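The alternatives of scores as deposited, limma-voom, title number series, libraries of low total or few rows, single lymphodepletion libraries left out, gamma-delta libraries 5 to 8 left out, and lung columns in their named order, which moved no count, were added after seeing the data; the others were planned. Of 262 counts under alternatives other than leaving out 1 library, 143 lay beyond 1.5 times the main count and the rest within; of the counts from leaving out 1 library, 44 lay within and 64 beyond. Named genes that passed kept direction and call in 847 of 1119 values, lost the call in 272 and turned in 0; those that did not pass stayed so in 340 of 353, passed in 9 and turned in 4. Those 4 were Cd3e against gamma-delta T cells (-0.0539 without combined ACT replicate 1, up to 1.19 without replicate 4, -0.32 under the replicate block and -0.32 without gamma-delta libraries 5 to 8) and Cd8a against LAK cells (-0.0630 without combined ACT replicate 1, up to 1.79 without replicate 2). The cause of a change was not tested except where an alternative leaves libraries out. Counts of 0 below are limma's unless limma-voom is named, with 508 to 4773 genes at an unadjusted p under 0.05 (838 to 2013 by limma-voom).

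With quantile normalization B16 triple called 8, anti-PD1 + TLR mix 70, TLR mix + ACT 245, anti-PD1 1, TLR mix 11 and ACT 2 against control; B16 TRI-IT called 0 against triple and 78 against anti-PD1 + TLR mix. CIK gave 4, subcutaneous TRI-IT against anti-PD1 5 and the interaction 341. Without a filter on low values B16 triple called 11, TLR mix 38, and TRI-IT 5 against triple, 3 against anti-PD1 + TLR mix and 1 against TLR mix + ACT; KP TRI-IT against triple gave 0, CIK 30 and subcutaneous TRI-IT against anti-PD1 9. With a pseudocount of 0.1 B16 TRI-IT called 5, triple 1, anti-PD1 + TLR mix 24, TLR mix 1, ACT 3, and TRI-IT 1 against triple and 9 against anti-PD1 + TLR mix. KP TRI-IT against triple gave 0, CTL 2, CIK 0, subcutaneous TRI-IT against anti-PD1 6 and the interaction 74.

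With only the groups compared in the fit, B16 TRI-IT called 0, triple 0, anti-PD1 + TLR mix 0, TLR mix + ACT 618, anti-PD1 2, TLR mix 0 and ACT 1, and TRI-IT 1 against triple, 0 against anti-PD1 + TLR mix and 0 against TLR mix + ACT. KP TRI-IT called 1384, triple 4, anti-PD1 + TLR mix 3, TLR mix + ACT 3876, anti-PD1 123, TLR mix 239, ACT 5 and lymphodepletion 4, and TRI-IT 0 against triple and 3801 against TLR mix + ACT. Gamma-delta gave 5, LAK 13, CTL 0, CIK 5 and the interaction 7. Without shallow libraries B16 TRI-IT called 708, triple 636, anti-PD1 + TLR mix 2323, TLR mix + ACT 1965, anti-PD1 20, TLR mix 365 and ACT 314, and TRI-IT 901 against anti-PD1 + TLR mix and 15 against TLR mix + ACT. KP triple called 742, anti-PD1 1949, TLR mix 2891, ACT 2252 and lymphodepletion 1492, TRI-IT 0 against triple and 2891 against TLR mix + ACT, and the interaction 2680.

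On the scores as deposited B16 TRI-IT called 46, triple 43, anti-PD1 + TLR mix 149, TLR mix + ACT 294, TLR mix 57 and ACT 52 higher and 52 lower (1.0e+02 in all), and TRI-IT 1 against triple, 55 against anti-PD1 + TLR mix and 21 against TLR mix + ACT. KP ACT called 2054, lymphodepletion 1461 and TRI-IT against triple 4. Gamma-delta, LAK and CTL gave 0 and CIK 7; inhaled TRI-IT gave 1553 against anti-PD1 and 2198 against subcutaneous, subcutaneous against anti-PD1 0 and the interaction 1128. By limma-voom B16 triple called 24, anti-PD1 + TLR mix 11, TLR mix + ACT 429 and ACT 0, and TRI-IT 0 against triple and 3228 against anti-PD1 + TLR mix. By limma-voom KP TLR mix + ACT called 14633, anti-PD1 2124, and TRI-IT 0 against triple and 3198 against TLR mix + ACT. By limma-voom gamma-delta gave 525, LAK 16, CTL 0 and CIK 0, and the correlation of fold changes between models was 0.1999.

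How far depth limits the B16 counts stays open, since leaving out control 3 (few rows, not shallow) beside the shallow libraries gave lower counts than leaving out the shallow ones alone for each B16 arm against control. With title numbers 46 to 74 only, B16 triple and ACT called 0. Without B16 libraries of low total or few rows TRI-IT called 91, triple 251, anti-PD1 + TLR mix 389, TLR mix + ACT 1069, anti-PD1 13, TLR mix 149 and ACT 47 higher and 70 lower (1.2e+02 in all), TRI-IT 4 against triple, 1862 against anti-PD1 + TLR mix and 62 against TLR mix + ACT, and the interaction 614. With title numbers from 75 up only, KP TRI-IT called 370, triple 1, anti-PD1 + TLR mix 20, anti-PD1 16, TLR mix 0, ACT 3, lymphodepletion 0 and TRI-IT against anti-PD1 + TLR mix 1. With the series as a term KP TRI-IT called 295, anti-PD1 + TLR mix 6, anti-PD1 12, TLR mix 14, ACT 5 and lymphodepletion 1. With the replicate number as a block gamma-delta gave 1, LAK 13 and CTL 1. Numbers 5 to 8 occur among gamma-delta libraries alone, so the block in effect leaves these out and is no separate check. Deviations from group means correlated at -0.24 to 0.08 between combined ACT libraries and others of the same number, so no pairing was seen. The gamma-delta deviations also hold the split of libraries 5 to 8, which could hide a pairing. Without gamma-delta libraries 5 to 8 gamma-delta gave 1, CTL 1 and CIK 2. Of 204 list tests camera called 66 with its preset correlation, 3 with an estimated correlation and fry 23.

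Leaving out 1 library gave counts from 16 to 54 for B16 TRI-IT, 0 to 16 for triple, 25 to 90 for anti-PD1 + TLR mix, 29 to 98 for TLR mix + ACT, 0 to 8 for anti-PD1, 0 to 62 for TLR mix, 6 to 52 for ACT and 1 to 6 for TRI-IT against triple. The ranges were 76 to 540 for KP anti-PD1, 578 to 951 for TLR mix, 506 to 707 for ACT and 83 to 541 for lymphodepletion. In the transfer table they were 6 to 412 for gamma-delta, 4 to 79 for LAK, 1 to 7 for CTL and 1 to 358 for CIK. In lung tumors they were 3100 to 3287 for inhaled TRI-IT against anti-PD1 and 2 to 10 for subcutaneous TRI-IT against anti-PD1, and the interaction ranged from 229 to 312.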

Other observations

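The tests with macrophage genes and without gamma-delta libraries 5 to 8 in this part were chosen after the results were seen. Some genes changed in ways the sample descriptions do not foresee. The heat shock gene Dnajb1 and the immediate early gene Fos differed between the routes, with Dnajb1 at 438 ± 89.1 in inhaled and 4222 ± 2729 in subcutaneous lung libraries and Fos at 87.6 ± 46.4 and 872 ± 444. Pigment cell genes were measured in lung tumors, with Dct at 120.4 ± 74.5 split reads after anti-PD1 (n = 4), 79.2 ± 15.3 after subcutaneous (n = 7) and 1.503 ± 2.19 after inhaled TRI-IT (n = 9). In melanomas Scd2 and Fdps, a pair of lipid synthesis genes with no list of their own, were lower after combined ACT than after gamma-delta T cells, at 1994 ± 308 against 3143 ± 524 and 498 ± 64.8 against 765 ± 124 split reads. Without gamma-delta libraries 5 to 8, 23 of 23 named calls of that comparison were lost, these included. Over 12 alternatives the fold change stayed at -0.740 to -0.474 for Scd2 and -0.698 to -0.433 for Fdps.

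One hypothesis was tested, that the interferon-gamma response of a tumor follows its T cell content. Within-group deviations of the list means of T cell and interferon-gamma genes had a Pearson r of 0.591 across the 21 transfer libraries (permutation p = 0.0046, adjusted over 2 relations 0.0046; Spearman rho 0.764, permutation p = 0.00016). Without the 2 farthest libraries r was 0.565. Across the 20 lung libraries r was 0.781 (permutation p = 5e-05, adjusted 0.0001; rho 0.817, permutation p = 4e-05) and 0.728 without the 2 farthest. Macrophage means followed the interferon-gamma means as well, with r of 0.659 in the transfer table (permutation p = 0.0011) and 0.433 in lung (permutation p = 0.056), and followed the T cell means with r of 0.560 and 0.726. Without gamma-delta libraries 5 to 8, which stand apart, r over 17 libraries was 0.502 for T cells and 0.641 for macrophages. The permutations shuffled the deviations over all libraries, ignoring the groups. Deviations within a group are tied to its mean, so these permutation p-values are likely too small. Combined ACT replicate 3 had the highest interferon-gamma mean of its group (8.95) with a T cell mean of 3.01, against 5.35 in replicate 1. The relations, with r of 0.591 and 0.781 for T cells, may reflect immune content as a whole, and they do not single out T cells as the source.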
